A study of Mus musculus with 16 samples.

How the data were processed

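The study measured poly(A) RNA of the mouse C2C12 myoblast line. Per the labels' protocols, MYOD-/- cells were made by CRISPR-Cas9 with screening of single cells, and an empty vector or a vector for spliced MUNC was stably transfected. RNA was purified with RNeasy columns, libraries were made with the NEBNext Ultra Directional kit, and pairs of 75-base reads were sequenced on a NextSeq. Per the submitters' processing notes, bcl2fastq and kallisto were run with RefSeq transcripts and the mm10 genome. Their versions, the strand setting of kallisto and the deleted part of Myod1 are not given in the sources used here. Fragments from genes that overlap on opposite strands, or from close paralogs such as Oas1a and Oas1g, could therefore have been assigned to either.

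The authors deposited 1 table per library. Per the file headers it holds the estimated counts and the effective length of each of 35818 transcripts, made by kallisto by dividing fragments that fit several transcripts. Per the file headers it also holds TPM, which the authors' kallisto run made from the estimated counts and effective lengths. Between 56.7% and 60.8% of the estimated counts, those of 0 included, were whole numbers (to within 1e-06). The 16 libraries were placed in 8 groups of 2 from their labels alone, and none was left out. Transcripts were assigned to genes through the RefSeq table of GRCm38.p6 (35492 transcripts) or GENCODE M21 metadata (188 transcripts), and 138 without a symbol were left out, with 0.280% to 0.941% of the counts. This gave 24497 genes, with 0 mitochondrial genes. MUNC was identified as Gm45923 by its synonym in the RefSeq table, and reads from the vector and from the cells' own gene were counted together. Coordinates are those of GRCm38, counted from 1.

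Estimated counts were summed over the transcripts of each gene and rounded. In R 4.3.3, edgeR 4.0.16 was used with TMM scaling and filterByExpr, which left 14972 genes, and 1 model with a mean per group was fitted to all 16 libraries (8 residual degrees of freedom, 3.19 prior degrees of freedom, common dispersion 0.0474). Each comparison used the quasi-likelihood F test with Benjamini-Hochberg adjustment over the 14972 genes and a threshold of 0.05. Differentiation was tested as DM minus GM, genotype as labelled MYOD-/- minus labelled WT, and MUNC as MUNC minus EV. Interactions were differences of these. SEs are those of the log2 fold change in this model. Where a gene had 0 counts in a group, CPM is given in place of a fold change. The analysis was checked on simulated counts with 200 changed genes, where it recovered 55% to 60% of genes changed 2-fold and 94% to 97% of genes changed 4-fold, and 3.87% to 6.55% of calls were false. The changed genes had a mean of at least 5 CPM, and counts were drawn independently, without a replicate effect common to the groups.

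Gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 26 lists. The same test with the correlation estimated from the data is given beside each list whose call it ends. The lists, with 532 different genes tested, were myogenic regulators, sarcomere and contractile, excitation-contraction and neuromuscular junction, muscle metabolism, myoblast fusion, cell cycle, cell cycle exit, inhibitors of myogenesis, satellite and reserve cell markers, imprinted genes, interstitial collagens and matrix, basement membrane and integrins, TGF-beta and smooth muscle, fibroblast-like, adipogenic, osteogenic and chondrogenic, endothelial, leukocyte, epithelial and neural, interferon response, cytokines and chemokines, immediate early and heat shock, p53 targets, sterol synthesis, unfolded protein response, and Wnt and Hox. Counts adjusted over the list alone used Benjamini-Hochberg adjustment within the list.

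The comparisons, tests, lists, alternatives and the rule for naming genes were written before the data were examined. The rule named a panel of 24 genes in every comparison. It also named the 5 genes with the largest change each way that passed the test, had a mean of at least 5 CPM and had both libraries of 1 group above both of the other. It further named up to 4 members of each list past the list test and 2 of each other list, and the 3 largest differences each way of an interaction with its panel genes past the threshold. The text gives examples of these, and 1 of the genes that the rule selects was withheld and is not reported here. In all 455 pairs of a named gene and a comparison it passed, both libraries of 1 group lay above both of the other. The rule required this of the largest changes, and passing the test makes it likely for the rest, so it is no separate check. Genes chosen after their values were seen are named as such.

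The alternatives were DESeq2 1.42.0, DESeq2's size factors within edgeR, no filter and a filter of 5 CPM in 2 libraries, transcripts in place of genes, effective length offsets, a fit on the compared groups only, replicate number as a block, robust dispersion, limma on log2(TPM + 1), a 2-fold threshold, an adjusted p threshold of 0.01, fry in place of camera, and leaving out each library. Chosen after seeing the data were leaving out Zrsr1 and Rn28s1, the block in a fit on the compared groups only, and the alternatives for named genes outside the panel. Overlaps of calls that share libraries were compared with independent lists and with 20 simulations of unchanged groups. With groups of 2 libraries no test over other groupings of the libraries was made, and no library was judged an outlier. Raw reads were not used here.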

Results

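RNA sequencing of poly(A) RNA was carried out on C2C12 cells, a mouse myoblast line that proliferates in growth medium (GM) and forms muscle fibres when moved to differentiation medium (DM). The labels divide 16 libraries into 8 groups of 2 by genotype (WT, or MYOD-/- made with CRISPR-Cas9), by vector (an empty vector, EV, or a vector for the spliced form of MUNC, a noncoding RNA) and by culture condition (GM or DM). The total estimated count per library ranged from 35.8 M to 108 M, with a median of 61.2 M. In the WT-labelled groups it was 62.7 M and 52.97 M (EV, GM), 83.9 M and 74.1 M (EV, DM), 63.4 M and 59.6 M (MUNC, GM), and 48.2 M and 108 M (MUNC, DM). In the knockout-labelled groups it was 35.8 M and 45.2 M (EV, GM), 49.9 M and 58.8 M (EV, DM), 64 M and 58.5 M (MUNC, GM), and 62.7 M and 83 M (MUNC, DM). Levels are given as TMM-scaled CPM, mean ± SD with n = 2, and changes as log2 fold change ± SE. The labels do not say whether the 2 replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

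The targeted gene, Myod1, which encodes a transcription factor that directs muscle differentiation, went against the genotype labels. Myod1 (GRCm38, chromosome 7, 46376474 to 46379092) stood at 0.155 ± 0.192 CPM in the proliferating and 0.0781 ± 0.0912 CPM in the differentiating EV libraries labelled WT, from 18, 1, 13 and 1 counts. In the EV libraries labelled MYOD-/-, Myod1 stood at 12.9 ± 1.39 CPM in GM and 28.8 ± 6.20 CPM in DM, from 519, 476, 1271 and 1858 counts. The MUNC libraries labelled WT held Myod1 at 3.89 ± 0.242 CPM (GM) and 2.44 ± 1.04 CPM (DM), below the 4 MUNC libraries labelled MYOD-/-, which held 8.17 and 4.18 (GM) and 16 and 15 CPM (DM). The deleted part of Myod1 is not given in the sources used here, so a deletion that leaves most of the transcript in place is not checked by these counts. Groups are therefore called WT-labelled and knockout-labelled throughout, and every direction between genotypes follows the labels. MUNC, listed as Gm45923 (chromosome 7, 46371403 to 46372492, an interval that does not overlap Myod1), reached 2023 ± 286 CPM (GM) and 2341 ± 465 CPM (DM) in the WT-labelled MUNC libraries. Its level in the knockout-labelled MUNC libraries was 119 ± 18.2 CPM (GM) and 46.7 ± 5.25 CPM (DM). In the EV libraries Gm45923 lay between 8.95 and 12.4 CPM in replicate 1 and between 1.15 and 2.23 CPM in replicate 2.

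**Figure D1:**
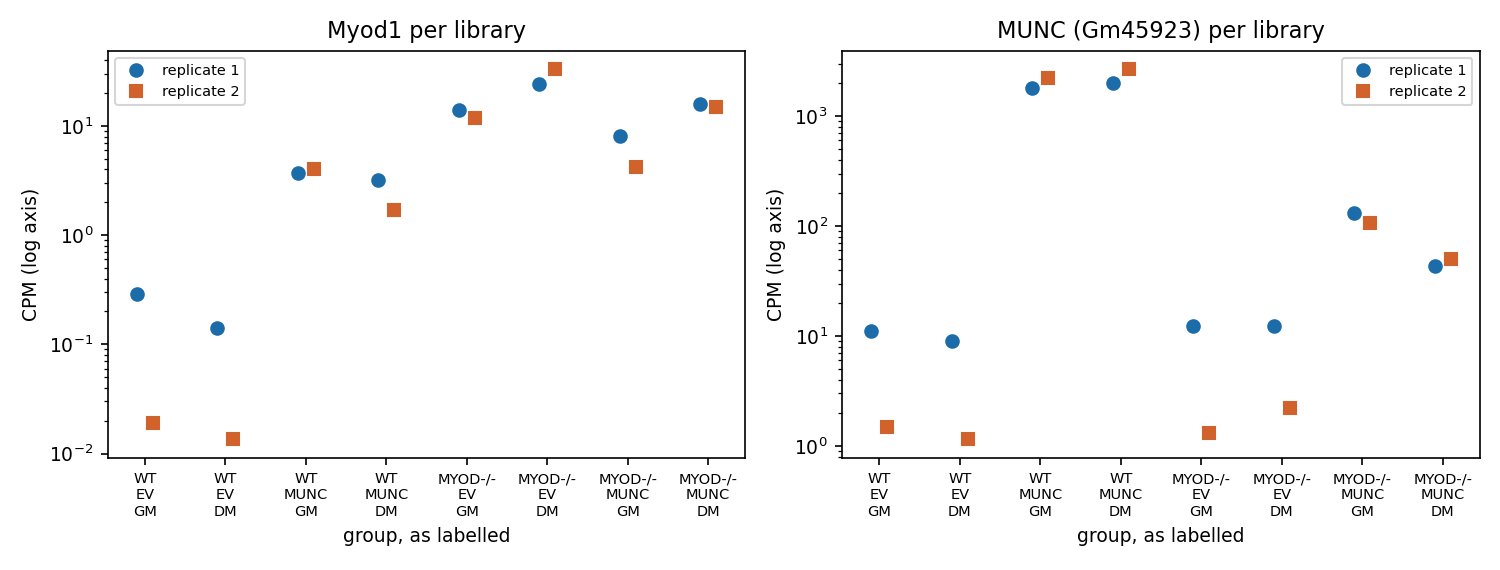
Level of Myod1 and of MUNC (Gm45923) in each library, in TMM-scaled CPM on a log axis, with 1 point per library and the groups along the x axis. Myod1 lies lowest in the 4 EV libraries labelled WT (0.0136 to 0.291 CPM), and MUNC reaches 1821 CPM or more only in the 4 MUNC libraries labelled WT.

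Log2 CPM of the 2 libraries of a group correlated at 0.973 to 0.992 across genes, which are not independent replicates, and their counts differed by far more than sampling noise (chi-square per degree of freedom 165 to 642). The first principal component, with 43.4% of the variance, separated DM from GM libraries. The second, with 21.1%, separated the 4 WT-labelled EV libraries from the other 12. The knockout-labelled EV and MUNC libraries of the same replicate and condition correlated at 0.991 to 0.994, and the WT-labelled EV and MUNC libraries at 0.919 to 0.967. Zrsr1, a splicing factor gene, took 1.49% to 13% of all counts in the 8 libraries of replicate 2 and 0.00795% to 0.0348% in the 8 of replicate 1. Every gene called in any comparison or interaction had the same sign of change within replicate 1 and within replicate 2. Passing the test with 2 libraries per group makes this likely, so it is no separate check of the calls.

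**Figure D2:**
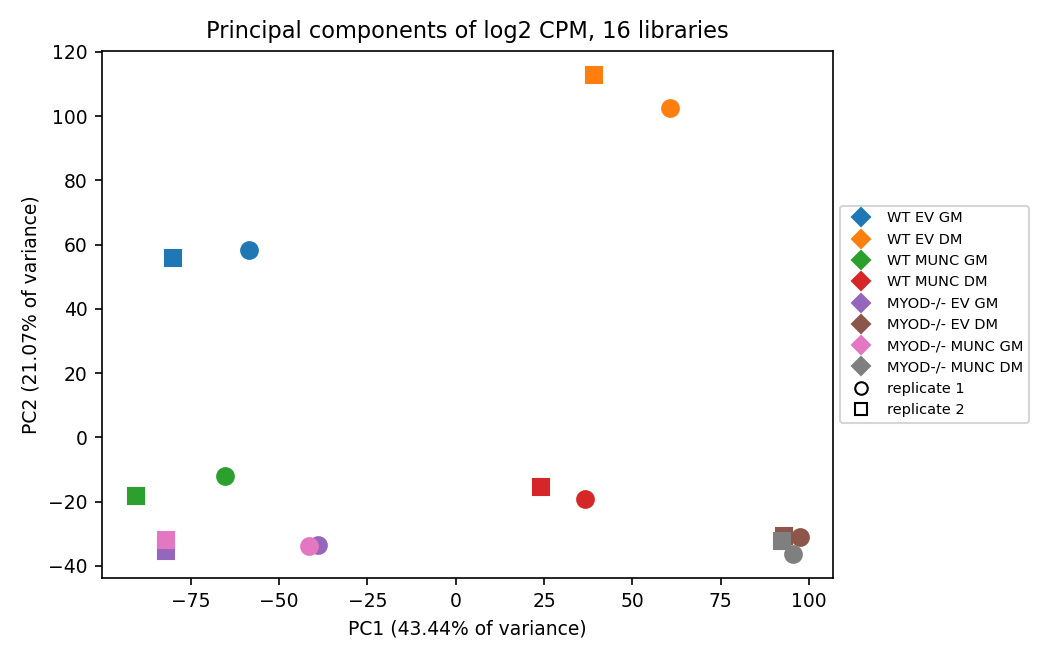
First and second principal components of log2 CPM, 1 point per library, coloured by group, with the percentage of variance on each axis. The DM libraries lie to the right of the GM libraries, and the 4 WT-labelled EV libraries lie above all others on the second component.

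Differentiation of the WT-labelled EV cells (DM against GM) was marked by loss of proliferation genes and gain of interferon-response genes. Mki67, a marker of cycling cells, fell from 533 ± 32.3 to 131 ± 15.6 CPM (log2 fold change -2.03 ± 0.22, adjusted p = 5.27e-05), and Ccnb1, the cyclin of mitotic entry, fell from 216 ± 2.13 to 41.1 ± 12.7 CPM (-2.39 ± 0.21, adjusted p = 1.47e-05). Dhx58, a cytoplasmic RNA sensor, rose from 1.22 ± 0.216 to 150 ± 4.04 CPM (6.94 ± 0.21, adjusted p = 2.04e-08). Oas1a, an enzyme that activates RNase L, rose from 0.184 ± 0.152 to 348 ± 19.4 CPM, with reads possibly shared with its paralog Oas1g. Among muscle genes, Myog, a transcription factor of terminal differentiation (chromosome 1, 134290004 to 134292548), rose from 0.0338 ± 0.0208 to only 0.948 ± 0.304 CPM (4.69 ± 0.88, adjusted p = 0.00179). Chrna1, the alpha subunit of the acetylcholine receptor, rose from 8.68 ± 7.94 to 68.8 ± 3.37 CPM (2.98 ± 0.57, adjusted p = 0.00201). Myh3, the embryonic myosin heavy chain, was at 0.233 ± 0.0595 CPM in GM and 0.737 ± 0.275 CPM in DM and did not pass (1.65 ± 0.71, adjusted p = 0.0910).

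All 31 interferon-response genes rose in this comparison, also when adjusted over the list alone (median log2 fold change 7.20, or 7.15 with a gene at 0 counts set to its bound; camera adjusted p = 3.62e-25, adjusted p = 0.260 with an estimated correlation). Among them Irf9, a subunit of the interferon-activated transcription factor, rose by 4.22 ± 0.20. Of the 50 cell cycle genes 49 fell (50 adjusted over the list alone; median -1.92, camera adjusted p = 3.62e-28, adjusted p = 0.296 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, is an example (-2.50 ± 0.14). Of 31 genes of excitation-contraction coupling and the neuromuscular junction 14 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.959 with an estimated correlation). They include Rapsn, which clusters acetylcholine receptors (1.64 ± 0.17), and Ryr1, the calcium release channel (2.19 ± 0.37). Of 19 TGF-beta and smooth muscle genes 9 fell (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0196, adjusted p = 0.679 with an estimated correlation). Acta2, smooth muscle actin, fell from 1411 ± 56.7 to 269 ± 69.9 CPM (-2.39 ± 0.51), and Tagln, an actin-binding protein, by 4.60 on the log2 scale (SE 0.43). The sarcomere list did not pass (camera adjusted p = 0.534), with 7 of 45 genes higher and 2 lower (4 and 1 adjusted over the list alone). Outside these lists, Agrn, which organises the neuromuscular synapse, rose by 3.26 ± 0.18, and Ddit3, a stress-response transcription factor, rose by 3.11 ± 0.25. Id3, an inhibitor of myogenic transcription factors, fell by 4.99 on the log2 scale (SE 1.09, adjusted p = 0.00428). Ly6a, a surface marker of fibroblast-like progenitors, rose from 56.8 ± 3.40 to 1996 ± 17.7 CPM. Across all 14972 genes tested, 2876 rose and 2742 fell (5618 in total, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with the same sign in both replicates for all 5618. With limma on log2(TPM + 1) the split was 3402 higher and 1913 lower. Mymk, which drives myoblast fusion, had 0 counts in GM and 0.183 ± 0.0669 CPM in DM (adjusted p = 0.0211), a call lost without GM replicate 1 (0.0904), GM replicate 2 (0.0800) or DM replicate 1 (0.0842). Tnnt3, fast troponin T, at 4.05 ± 1.10, and the growth factor Igf2, at 3.54 ± 1.16, lost theirs without GM replicate 2 (0.0999 and 0.174) or DM replicate 1 (0.158 and 0.252), and Runx2 kept its fall (-0.87 ± 0.15). The cell cycle inhibitor Cdkn1a (0.56 ± 0.20, adjusted p = 0.0490) lost its call without any 1 of the 4 libraries (GM 0.0969 and 0.215, DM 0.0521 and 0.232).

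In the knockout-labelled EV cells the same change of medium brought up the contractile programme. Myh3 (chromosome 11, 67078273 to 67102291) rose from 0.142 ± 0.0117 to 223 ± 21.4 CPM (10.60 ± 0.80, adjusted p = 6.79e-06), and Myog rose from 0.223 ± 0.139 to 23.1 ± 1.58 CPM (6.69 ± 0.70, adjusted p = 3.90e-05). Mymk (chromosome 2, 27061636 to 27072161) rose from 0.607 ± 0.504 to 19.7 ± 0.835 CPM (5.03 ± 0.64, adjusted p = 0.000191). The skeletal actin gene Acta1 rose by 4.52 ± 1.06, Tnnt3 by 6.47 ± 1.10 and Ckm, muscle creatine kinase, by 6.11 ± 1.04. Mki67 fell by 1.42 and Ccnb1 by 2.42 on the log2 scale (SE 0.22 and 0.21). Dhx58 rose from 0.593 ± 0.0822 to 65.6 ± 1.77 CPM (6.78 ± 0.21, adjusted p = 4.08e-08), and Irf7, a transcription factor of the interferon response, rose from 0.496 ± 0.169 to 183 ± 4.30 CPM.

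By list, 35 of 45 sarcomere genes rose here (37 higher and 1 lower adjusted over the list alone; median 4.33, camera adjusted p = 2.01e-11, adjusted p = 0.193 with an estimated correlation). Mylpf, a fast myosin light chain (6.30 ± 0.39), and Tmod1, which caps thin filaments (5.76 ± 0.36), are examples. All 31 interferon genes rose, also adjusted over the list alone (median 6.89, camera adjusted p = 1.82e-21, adjusted p = 0.193 with an estimated correlation). Of 50 cell cycle genes 48 fell, also adjusted over the list alone (median -1.66, camera adjusted p = 9.89e-23, adjusted p = 0.243 with an estimated correlation). Of the excitation-contraction list 21 of 31 rose (23 adjusted over the list alone; camera adjusted p = 3.97e-05, adjusted p = 0.337 with an estimated correlation), with Ryr1 at 5.11 ± 0.36. Satellite and reserve cell markers (7 of 17 higher, also adjusted over the list alone) passed with camera adjusted p = 0.0246, and adjusted p = 0.248 with an estimated correlation. Another 6 lists passed at camera adjusted p = 0.0285. These were muscle metabolism (11 higher and 2 lower of 22; 12 and 2 adjusted over the list alone; adjusted p = 0.337 with an estimated correlation) and myoblast fusion (10 and 1 of 22; 10 and 2 adjusted over the list alone; 0.254). Interstitial collagens and matrix had 12 higher and 3 lower of 35 (13 and 3 adjusted over the list alone; adjusted p = 0.597 with an estimated correlation). Basement membrane and integrins had 7 higher of 20 (7 adjusted over the list alone; 0.243), with Agrn at 3.58 ± 0.18. Sterol synthesis had 5 higher of 24 (5 adjusted over the list alone; adjusted p = 0.697 with an estimated correlation). The unfolded protein response had 1 higher and 7 lower of 20 (1 and 6 adjusted over the list alone; 0.597), with Atf4, its central transcription factor, at -1.03 ± 0.17. In total 6470 genes changed, 3522 higher and 2948 lower, and 4292 did without GM replicate 2. With limma on log2(TPM + 1) the split was 4719 higher and 1908 lower. Without GM replicate 2 the calls of Chrna1 (1.98 ± 0.55; 0.0992), Cdkn1a (0.78 ± 0.21; 0.129), Id3 (-2.82 ± 0.98; 0.268), Igf2 (3.90 ± 1.27; 0.164), Runx2 (-0.51 ± 0.15; 0.0735) and Acta2 (1.36 ± 0.50; 0.223) were lost, the adjusted p without it being given last. Without DM replicate 2 these 6 had adjusted p of 0.0531, 0.0962, 0.179, 0.0578, 0.0779 and 0.140. Without DM replicate 1 Id3, Igf2, Runx2 and Acta2 were lost too (0.0994, 0.0843, 0.0724 and 0.114), and Acta2 was also lost without GM replicate 1 (0.0995) and with DESeq2's size factors (0.0513).

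**Figure D3:**
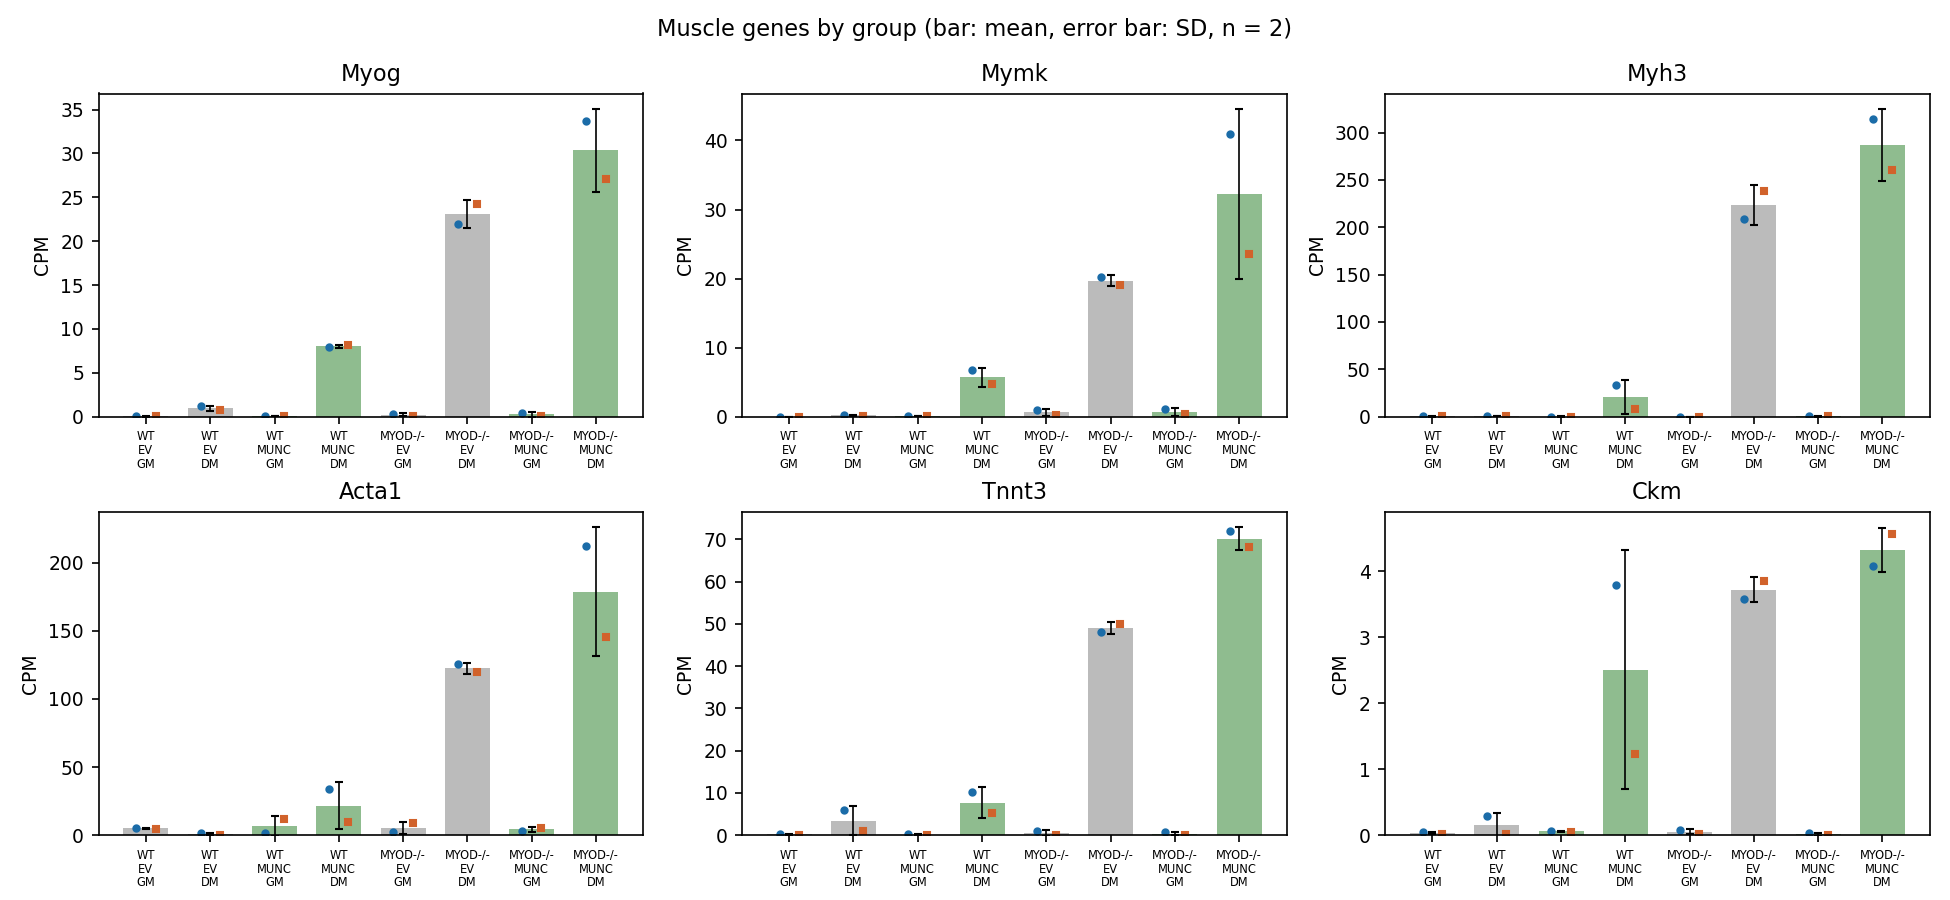
Levels of Myog, Mymk, Myh3, Acta1, Tnnt3 and Ckm in the 8 groups, in TMM-scaled CPM, 1 panel per gene, where bars are means, error bars SD (n = 2) and points single libraries. Myh3 stands at 223 ± 21.4 CPM in the differentiating knockout-labelled EV libraries and at 0.737 ± 0.275 CPM in the WT-labelled ones.

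The difference between these differentiation responses was tested as an interaction (change in knockout-labelled minus change in WT-labelled EV cells). Tagln differed by 5.52 ± 0.56 (adjusted p = 0.00136), since it fell in the WT-labelled cells only, and Cd53, a leukocyte tetraspanin, by -6.80 ± 0.91 (adjusted p = 0.00512). Myh3 differed by 8.94 ± 1.21 (adjusted p = 0.00522), a call lost without the WT-labelled GM replicate 1 (0.0520). Acta1 differed by 7.30 ± 1.49 (adjusted p = 0.0298), with adjusted p between 0.0650 and 0.122 when any of 7 libraries was left out, and Acta2 by 3.75 ± 0.71 (adjusted p = 0.0224), with 0.0533 to 0.106 when any of the same 7 was left out. The library that kept both calls was the WT-labelled DM replicate 1. The sarcomere list responded more strongly in the knockout-labelled cells, with 11 of 45 genes higher (16 adjusted over the list alone; median 3.08, camera adjusted p = 3.95e-20). Its call held with an estimated correlation (adjusted p = 0.0215), as did those of the basement membrane list (3 higher of 20, 9 adjusted over the list alone) and the myoblast fusion list (0 of 22 over all genes, 6 adjusted over the list alone). TGF-beta and smooth muscle genes (5 of 19 higher, 7 adjusted over the list alone) passed with the preset correlation only (camera adjusted p = 6.22e-05, adjusted p = 0.128 with an estimated correlation). The lists given for this and the other interactions are examples of those that passed. Of all genes, 249 responded more positively and 138 more negatively in the knockout-labelled cells (387 in total). DESeq2 gave 507 and 485, and an adjusted p threshold of 0.01 gave 42 and 14. The count fell to 204 and 73 without the WT-labelled GM replicate 1 and 2, 63 without the WT-labelled DM replicate 2, 250 and 90 without the knockout-labelled GM replicate 1 and 2, and 57 and 96 without the knockout-labelled DM replicate 1 and 2. Without the WT-labelled DM replicate 1 it was 333 and the direction of the split turned, with 152 higher and 181 lower.

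The genotype comparison asked which genes differ between knockout-labelled and WT-labelled EV cells. In proliferating cells Myod1 was higher in the knockout-labelled libraries (6.29 ± 0.75, adjusted p = 0.000385), against the label. Chrna1 was also higher, at 144 ± 32.3 against 8.68 ± 7.94 CPM (4.05 ± 0.60, adjusted p = 0.00157), as was Dysf, a membrane repair protein, at 4.45 ± 0.371 against 0.189 ± 0.0838 CPM (4.57 ± 0.31, adjusted p = 1.73e-05). Igfbp2, which binds insulin-like growth factors (9.62 ± 1.11), and Cd34, a progenitor surface marker (5.22 ± 0.65), were higher. Perp, a p53-regulated desmosomal protein (chromosome 10, 18845071 to 18857073), was at 21.9 ± 4.11 CPM in WT-labelled and 0.0125 ± 0.0177 CPM in knockout-labelled cells (-10.52 ± 0.78, adjusted p = 2.31e-05). Bckdhb, an enzyme subunit of branched-chain amino acid breakdown, was at 11.5 ± 1.52 CPM against 0 counts. Isg15, an interferon-induced ubiquitin-like protein (-3.44 ± 0.45), and the chemokine Cxcl10 (-4.09 ± 0.51) were lower. Of 31 interferon genes 11 were lower (15 adjusted over the list alone; median -1.33, camera adjusted p = 1.63e-06, adjusted p = 0.652 with an estimated correlation). The excitation-contraction list (4 higher and 1 lower of 31; 5 and 1 adjusted over the list alone; adjusted p = 0.763 with an estimated correlation) and the p53 targets (3 lower of 21, also adjusted over the list alone; adjusted p = 0.652 with an estimated correlation) each passed at camera adjusted p = 0.0156. Among the lower p53 targets, Perp apart, were Ei24 and Cdkn1a, at -0.62 ± 0.15 and -0.72 ± 0.20. In total 686 genes were higher and 864 lower (1550, all with the same sign in both replicates). The count was 753 and 702 without the WT-labelled GM replicate 1 and 2, and 849 (474 higher and 375 lower) and 732 (445 and 287) without the knockout-labelled ones. The calls of Ei24 and Cdkn1a were lost without any 1 of the 4 libraries (in the same order 0.0934, 0.105, 0.0508 and 0.210 for Ei24, and 0.203, 0.110, 0.0897 and 0.283 for Cdkn1a), and Cdkn1a also with no filter on low counts (0.0585) and with DESeq2's size factors (0.0563). Mymk, at 0.607 ± 0.504 CPM against 0 counts (adjusted p = 0.00992), lost its call without WT-labelled replicate 1 (0.0618), WT-labelled replicate 2 (0.0532) or knockout-labelled replicate 1 (0.0588).

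In differentiating EV cells the knockout-labelled libraries held more muscle transcripts. Myod1 was 8.40 ± 0.81 higher on the log2 scale (adjusted p = 3.91e-05), Myh3 8.22 ± 0.67 (adjusted p = 1.36e-05) and Mymk 6.71 ± 0.69 (adjusted p = 0.000103). Myog was at 23.1 ± 1.58 against 0.948 ± 0.304 CPM (4.60 ± 0.59, adjusted p = 0.000244), and Acta1 at 122 ± 4.11 against 0.721 ± 0.732 CPM (7.36 ± 1.23, adjusted p = 0.00116). Ckm (4.56 ± 0.84), Chrna1 (3.05 ± 0.57) and Acta2 (2.91 ± 0.52) were higher as well. Lower in the knockout-labelled cells were Mx1, an antiviral GTPase, at 7.74 ± 1.84 against 83.7 ± 12.1 CPM (-3.43 ± 0.35, adjusted p = 5.27e-05), and Ddit3 (-2.20 ± 0.24). Perp was again near 0 in the knockout-labelled and at 17.2 ± 0.167 CPM in the WT-labelled cells (-10.58 ± 0.77). Tnnt3 (3.82 ± 0.91, adjusted p = 0.00911) lost its call without the WT-labelled DM replicate 2 (0.0583).

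Of the lists, sarcomere (32 of 45 higher, 36 adjusted over the list alone; median 3.97, camera adjusted p = 2.45e-16), myoblast fusion (15 of 22, 16 adjusted over the list alone; camera adjusted p = 6.63e-07) and basement membrane (11 higher and 1 lower of 20, 13 and 2 adjusted over the list alone; camera adjusted p = 0.000281) kept their calls with an estimated correlation (adjusted p = 0.0385 for each). Dysf (5.83 ± 0.30) and Col4a1, a basement membrane collagen (2.50 ± 0.32), are examples. Another 9 lists passed with the preset correlation only. Excitation-contraction had 16 higher and 2 lower of 31 (19 and 2 adjusted over the list alone; camera adjusted p = 2.58e-05, adjusted p = 0.317 with an estimated correlation). TGF-beta and smooth muscle had 11 higher of 19 (12 adjusted over the list alone; camera adjusted p = 0.00239, adjusted p = 0.271 with an estimated correlation). Satellite and reserve cells had 8 higher and 1 lower of 17 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00274, adjusted p = 0.160 with an estimated correlation). Myogenic regulators had 6 higher of 16 (6 adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.271 with an estimated correlation). Muscle metabolism had 8 higher and 3 lower of 22 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0329, adjusted p = 0.319 with an estimated correlation). Wnt and Hox had 6 higher and 1 lower of 22 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0383, adjusted p = 0.375 with an estimated correlation). The interferon list had 18 of 31 lower (18 adjusted over the list alone; median -1.29, camera adjusted p = 0.000111, adjusted p = 0.375 with an estimated correlation). The unfolded protein response had 10 of 20 lower (11 adjusted over the list alone; camera adjusted p = 9.51e-05, adjusted p = 0.319 with an estimated correlation), with Pdia6, a protein disulfide isomerase, at -1.29 ± 0.13. The p53 targets had 8 of 21 lower (8 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.319 with an estimated correlation).

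The other 14 lists did not pass in this comparison, and their counts of higher and lower genes were the same adjusted over the list alone except for sterol synthesis, which had 2 and 0 of 24 (1 and 0 adjusted over the list alone). They were cell cycle (10 and 3 of 50), cell cycle exit (2 and 1 of 14), inhibitors of myogenesis (2 and 1 of 20), imprinted genes (2 and 1 of 11), interstitial collagens (9 and 1 of 35), immediate early and heat shock genes (1 and 4 of 22), and cytokines and chemokines (1 and 5 of 16). Lists for other cell types held 6 and 2 of 17 (fibroblast-like), 2 and 0 of 14 (adipogenic), 1 and 3 of 11 (osteogenic and chondrogenic), 1 and 1 of 6 (endothelial), 0 and 3 of 7 (leukocyte) and 2 and 4 of 12 (epithelial and neural). The 3 lower leukocyte genes include Cd74, which chaperones MHC class II (0.869 ± 0.0182 against 16.7 ± 1.20 CPM), and the lower epithelial genes include Krt8, a keratin (0.966 ± 0.173 against 14.4 ± 3.15 CPM). In total 2290 genes were higher and 2411 lower (4701, all with the same sign in both replicates), and limma on log2(TPM + 1) gave 2527 and 1710. The total was 2724 without the WT-labelled DM replicate 2, and 2635 and 2607 without the knockout-labelled DM replicate 1 and 2.

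MUNC and EV libraries were then compared within the WT-labelled cells. In proliferating cells Gm45923 itself was higher by 8.33 ± 1.5 (adjusted p = 0.00399), and Myod1 rose from 0.155 ± 0.192 to 3.89 ± 0.242 CPM (4.56 ± 0.73, adjusted p = 0.00192). Chrna1 rose from 8.68 ± 7.94 to 63.5 ± 32.4 CPM (2.87 ± 0.57, adjusted p = 0.00698), Dysf by 4.15 ± 0.31, and Musk, the receptor kinase of the neuromuscular junction, by 4.91 ± 0.76. Pparg, a transcription factor of fat cell formation, rose by 2.42 ± 0.25 (adjusted p = 0.000101). Some genes went from clear expression to almost none, or the reverse. Perp fell from 21.9 ± 4.11 to 0.0158 ± 0.0224 CPM, Peg10 (chromosome 6, 4747306 to 4760517) from 39.0 ± 6.43 to 0.0950 ± 0.134 CPM, and Sgce, its imprinted neighbour (chromosome 6, 4674350 to 4747204), from 18.6 ± 2.65 to 0.232 ± 0.277 CPM. Itpkb, an inositol phosphate kinase, rose from 0.0162 ± 0.0229 to 11.6 ± 3.57 CPM (9.23 ± 0.67, adjusted p = 1.28e-05).

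Interferon-related genes were lower with MUNC already in these proliferating cells, where Isg15 fell by 4.37 and Cxcl10 by 6.67 on the log2 scale (SE 0.47 and 0.62). Against the same WT-labelled EV libraries, Isg15, Cxcl10 and part of the interferon list were also lower in knockout-labelled EV cells, which had no MUNC vector. Of 31 interferon genes 13 were lower (17 adjusted over the list alone; median -1.98, camera adjusted p = 5.31e-07, adjusted p = 0.373 with an estimated correlation). Of 16 cytokines and chemokines 4 were lower (4 adjusted over the list alone; camera adjusted p = 0.0231, adjusted p = 0.358 with an estimated correlation). Sterol synthesis genes were higher as a list (2 of 24 called, 4 adjusted over the list alone; median 0.82, camera adjusted p = 3.40e-05, adjusted p = 0.580 with an estimated correlation). Another 4 lists passed at camera adjusted p = 0.0363, namely myoblast fusion (3 of 22 higher, 4 adjusted over the list alone), basement membrane (3 higher and 1 lower of 20, also adjusted over the list alone), epithelial and neural (2 of 12 lower, also adjusted over the list alone) and p53 targets (1 of 21 lower, also adjusted over the list alone), the last being Perp. With an estimated correlation their adjusted p was 0.358, 0.358, 0.358 and 0.539. Itga3, an integrin counted among the fusion genes, rose by 0.98 ± 0.18 (adjusted p = 0.00409). The only panel genes past the test were Myod1 and Chrna1, while Myog (1.07 ± 1.27), Myh3 (-1.09 ± 0.99) and Mki67 (-0.12 ± 0.21) were not. In total 905 genes were higher and 1154 lower (2059, all with the same sign in both replicates). The count was 993 and 1133 without the EV replicate 1 and 2, and 1199 and 970 without the MUNC replicate 1 and 2.

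In differentiating WT-labelled cells MUNC libraries had higher levels of some muscle genes and far lower levels of interferon-response genes. Gm45923 was higher by 8.85 ± 1.53 (adjusted p = 0.00123) and Myod1 by 4.83 ± 0.76 (adjusted p = 0.000669). Myog rose from 0.948 ± 0.304 to 8.03 ± 0.164 CPM (3.07 ± 0.55, adjusted p = 0.00158), Mymk from 0.183 ± 0.0669 to 5.73 ± 1.38 CPM (4.93 ± 0.66, adjusted p = 0.000331), and Myh3 from 0.737 ± 0.275 to 20.5 ± 17.9 CPM (4.78 ± 0.58, adjusted p = 0.000126). Ckm (3.98 ± 0.83) and Id3 (5.15 ± 1.10) rose too. Dhx58 (chromosome 11, 100694884 to 100704271) fell from 150 ± 4.04 to 1.11 ± 0.102 CPM (-7.09 ± 0.21, adjusted p = 1.68e-08), and Usp18, which removes ISG15 from proteins, from 422 ± 37.4 to 0.157 ± 0.167 CPM (-11.70 ± 0.61). Isg15 stood at 5.42 ± 0.718 CPM against 703 ± 100 CPM with EV. Tnnt3, at 7.70 ± 3.61 against 3.44 ± 3.43 CPM, did not pass (1.14 ± 0.84, adjusted p = 0.326), nor did Mki67 (0.51 ± 0.22, adjusted p = 0.0926).

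All 31 interferon genes fell, also adjusted over the list alone (median -7.32, camera adjusted p = 6.75e-27, adjusted p = 0.0709 with an estimated correlation). Of 22 myoblast fusion genes 12 rose (13 adjusted over the list alone; camera adjusted p = 3.07e-05, adjusted p = 0.0709 with an estimated correlation), with Dysf at 5.82 ± 0.30 and Cd9, a fusion-related tetraspanin, at 1.41 ± 0.15. Of 20 basement membrane genes 13 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.000958, adjusted p = 0.0709 with an estimated correlation). Of 45 sarcomere genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.95, camera adjusted p = 0.000399, adjusted p = 0.363 with an estimated correlation). Myogenic regulators (3 of 16 higher, 2 adjusted over the list alone; camera adjusted p = 0.306), excitation-contraction (11 higher and 3 lower of 31, 14 and 4 adjusted over the list alone; 0.0609) and muscle metabolism (7 and 3 of 22, 9 and 4 adjusted over the list alone; 0.0801) did not pass. Of 20 unfolded protein response genes 12 fell (12 adjusted over the list alone; camera adjusted p = 0.000316, adjusted p = 0.403 with an estimated correlation). Ddit3 (-2.74 ± 0.24) and Asns, asparagine synthetase (-2.89 ± 0.34), are among them. The list of interstitial collagens (9 higher and 2 lower of 35; 11 and 2 adjusted over the list alone; camera adjusted p = 0.00805, adjusted p = 0.447 with an estimated correlation) and the fibroblast-like list (8 and 3 of 17, also adjusted over the list alone; camera adjusted p = 0.0248, adjusted p = 0.477 with an estimated correlation) passed as higher. In the latter S100a4, a calcium-binding protein, rose (2.07 ± 0.16), and Ly6a fell (-4.57 ± 0.51). Sterol synthesis had 4 of 24 higher, also adjusted over the list alone (camera adjusted p = 0.0130, adjusted p = 0.619 with an estimated correlation). Lower were cytokines and chemokines (1 higher and 7 lower of 16; 1 and 8 adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.257 with an estimated correlation), leukocyte genes (4 of 7 lower, also adjusted over the list alone; camera adjusted p = 0.0305, adjusted p = 0.257 with an estimated correlation) and p53 targets (3 higher and 13 lower of 21; 3 and 14 adjusted over the list alone; camera adjusted p = 0.0248, adjusted p = 0.408 with an estimated correlation). Ctss, a lysosomal protease counted among the leukocyte genes, fell by 6.85 on the log2 scale (SE 0.50). In total 2337 genes were higher and 2643 lower (4980, all with the same sign in both replicates), against 3250 without EV replicate 2 and 3161 and 3140 without MUNC replicate 1 and 2. Without EV replicate 2, Acta1 (4.86 ± 1.11; 0.0562), Acta2 (2.17 ± 0.51; 0.0687), Igf2 (3.31 ± 1.09; 0.194), Cdkn1a (-0.58 ± 0.20; 0.258) and Chrna1 (1.82 ± 0.54; 0.117) lost their calls, the adjusted p without it being given last. Chrna1 also lost its call without EV replicate 1 (0.0883), MUNC replicate 1 (0.0581) or MUNC replicate 2 (0.0942), Cdkn1a without MUNC replicate 1 (0.325), and Igf2 without MUNC replicate 1 (0.153) or 2 (0.0701) and with DESeq2 (0.0503).

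**Figure D4:**
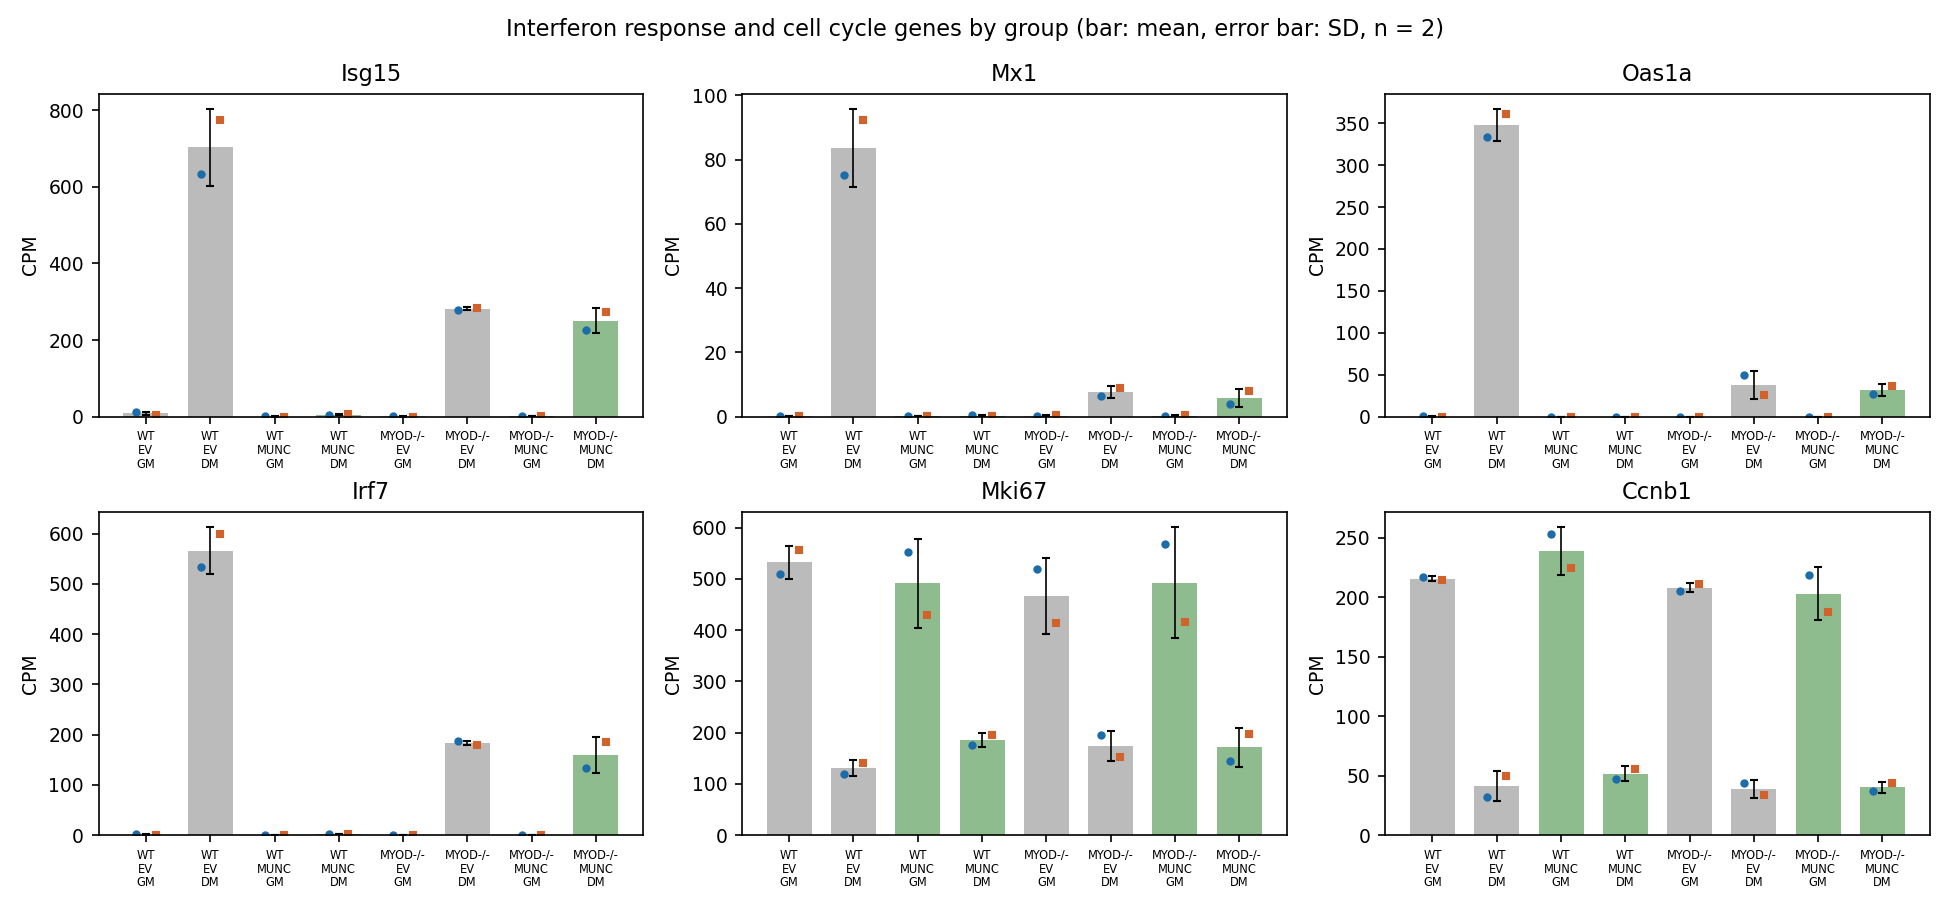
Levels of Isg15, Mx1, Oas1a, Irf7, Mki67 and Ccnb1 in the 8 groups, in TMM-scaled CPM, 1 panel per gene, where bars are means, error bars SD (n = 2) and points single libraries. Isg15 stands at 703 ± 100 CPM in the differentiating WT-labelled EV libraries and at 5.42 ± 0.718 CPM in the WT-labelled MUNC ones, while the knockout-labelled libraries hold 282 ± 3.61 (EV) and 251 ± 33.4 CPM (MUNC).

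In the knockout-labelled cells no gene passed the same test, which leaves out the replicate number, between MUNC and EV libraries. Gm45923 differed by 4.11 ± 1.25 in GM (unadjusted p = 0.00702, adjusted p = 1) and 2.68 ± 1.17 in DM (unadjusted p = 0.0428, adjusted p = 1). In DM, Myh3 was at 287 ± 38.0 against 223 ± 21.4 CPM (0.36 ± 0.47), Myog at 30.4 ± 4.71 against 23.1 ± 1.58 CPM (0.40 ± 0.50) and Mki67 at 171 ± 37.9 against 174 ± 29.6 CPM (-0.02 ± 0.21), each with adjusted p = 1. Isg15 (-0.17 ± 0.36) and Irf7 (-0.20 ± 0.35) likewise had adjusted p = 1, and Myod1 differed by -1.06 ± 0.55 in GM and -0.89 ± 0.54 in DM (adjusted p = 1). edgeR's quasi-likelihood test called 0 genes in GM (191 at an unadjusted p under 0.05; DESeq2 called 0, with 135 at an unadjusted p under 0.05) and 0 in DM (152 and a smallest adjusted p of 0.110; DESeq2 called 4, with 103). The other fits on all genes without the replicate number in the model called 0 to 4 genes. With the replicate number as a block, the fit on all 16 libraries called 0 in DM. The same block in a fit on the DM groups compared only, chosen after the data were seen, called 106 (53 higher and 53 lower), with Gm45923 at 3.03. Without the block, the fit on the DM groups compared only called 1. The 106 calls thus came with the block and the smaller fit together, and with neither alone. The DESeq2 calls in DM, named after their values were seen, were Dpep1, a membrane dipeptidase (2.23, adjusted p = 3.72e-09), Chst7, a sulfotransferase (-2.65), the uncharacterised 4933406F09Rik (4.02) and Astn2 (3.02). On simulated counts of the DM comparison the test recovered 57% of genes changed 2-fold and 95% of those changed 4-fold among 200. These rates hold for genes with a mean of at least 5 CPM and independent counts, without a replicate effect common to the groups. In DM the sterol synthesis list (median -0.31, camera adjusted p = 1.73e-06), the interferon list (-0.20, 0.00305) and the unfolded protein response list (0.14, 0.0386) passed, with no member called over all genes or adjusted over the list alone, and each had adjusted p = 0.990 with an estimated correlation. No list passed in GM.

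Whether the MUNC comparison differed between genotype labels was tested as an interaction (knockout-labelled minus WT-labelled). In proliferating cells Myod1 differed by -5.63 ± 0.91 (adjusted p = 0.00490), Peg10 by 8.52 ± 1.06 (adjusted p = 0.00103) and Itpkb by -8.71 ± 0.80 (adjusted p = 0.000200). Nbea (7.59 ± 0.98), Nefm, a neurofilament (6.41 ± 1.20), and the ephrin receptor Epha4 (-7.60 ± 0.71) were also among the largest differences. In differentiating cells Myod1 differed by -5.72 ± 0.94 (adjusted p = 0.00191), Mymk by -4.22 ± 0.82 (adjusted p = 0.00596), Myh3 by -4.41 ± 0.73 (adjusted p = 0.00203) and Oas1a by 12.07 ± 0.68 (adjusted p = 4.52e-06). All 31 interferon genes passed as higher, also adjusted over the list alone (median 7.05, camera adjusted p = 5.36e-29, adjusted p = 0.0611 with an estimated correlation). Of 22 fusion genes 7 were lower (7 adjusted over the list alone; camera adjusted p = 5.30e-05, adjusted p = 0.0611 with an estimated correlation). Of 45 sarcomere genes 9 were lower (12 adjusted over the list alone; camera adjusted p = 0.00176, adjusted p = 0.360 with an estimated correlation). In GM 5 of 31 interferon genes were higher (15 adjusted over the list alone; camera adjusted p = 7.31e-08, adjusted p = 0.361 with an estimated correlation). In DM, Myog (-2.68 ± 0.73, adjusted p = 0.0270), Ckm (-3.76 ± 1.06, 0.0307), Id3 (-5.12 ± 1.39, 0.0267) and Acta2 (-2.29 ± 0.70, 0.0430) passed with all libraries. Id3 and Acta2 lost their calls without any 1 of the 8 libraries (adjusted p 0.0504 to 0.114 and 0.0649 to 0.146), Myog without any but the WT-labelled EV replicate 1 (0.0702 to 0.118), and Ckm without any but the WT-labelled EV replicate 1 and MUNC replicate 2 (0.0570 to 0.130). The interaction passed for 413 genes higher and 324 lower in GM (737) and 1509 higher and 1199 lower in DM (2708). The GM count was 428 and 449 without the WT-labelled EV replicate 1 and 2, 396 without the WT-labelled MUNC replicate 2, and 452 and 443 without the knockout-labelled EV replicate 1 and 2. The DM count was 1794 without the WT-labelled EV replicate 2, 1762 and 1582 without the WT-labelled MUNC replicate 1 and 2, 1785 and 1515 without the knockout-labelled EV replicate 1 and 2, and 1637 without the knockout-labelled MUNC replicate 2.

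The MUNC comparison was also set between culture conditions (DM minus GM). In WT-labelled cells Prg4, a lubricating proteoglycan (7.17 ± 0.69, adjusted p = 0.000315), and Lix1 (5.89 ± 0.89, adjusted p = 0.00477) had more positive MUNC differences in DM. Of 31 interferon genes 23 had more negative ones (28 adjusted over the list alone; median -5.12, camera adjusted p = 9.54e-39, adjusted p = 0.0777 with an estimated correlation). Of 45 sarcomere genes 5 had more positive ones (9 positive and 1 negative adjusted over the list alone; camera adjusted p = 1.61e-06, adjusted p = 0.235 with an estimated correlation). Myh3 differed by 5.87 ± 1.14 (adjusted p = 0.0186), but not without the EV GM replicate 1 (0.114) or 2 (0.0702), the EV DM replicate 2 (0.0553) or the MUNC GM replicate 1 (0.0524) or 2 (0.0606). In total 186 genes were higher and 313 lower (499), or 45 and 131 at an adjusted p threshold of 0.01. The count was 327 and 212 without EV GM replicate 1 and 2, 251 without EV DM replicate 2, 198 and 308 without MUNC GM replicate 1 and 2, and 205 and 268 without MUNC DM replicate 1 and 2. In knockout-labelled cells the test called 0 genes (114 at an unadjusted p under 0.05; DESeq2 called 0, with 76). There the interferon list (camera adjusted p = 0.000168) and the cell cycle list (0.0201) passed with no member called, and both had adjusted p = 0.960 with an estimated correlation.

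**Figure D5:**
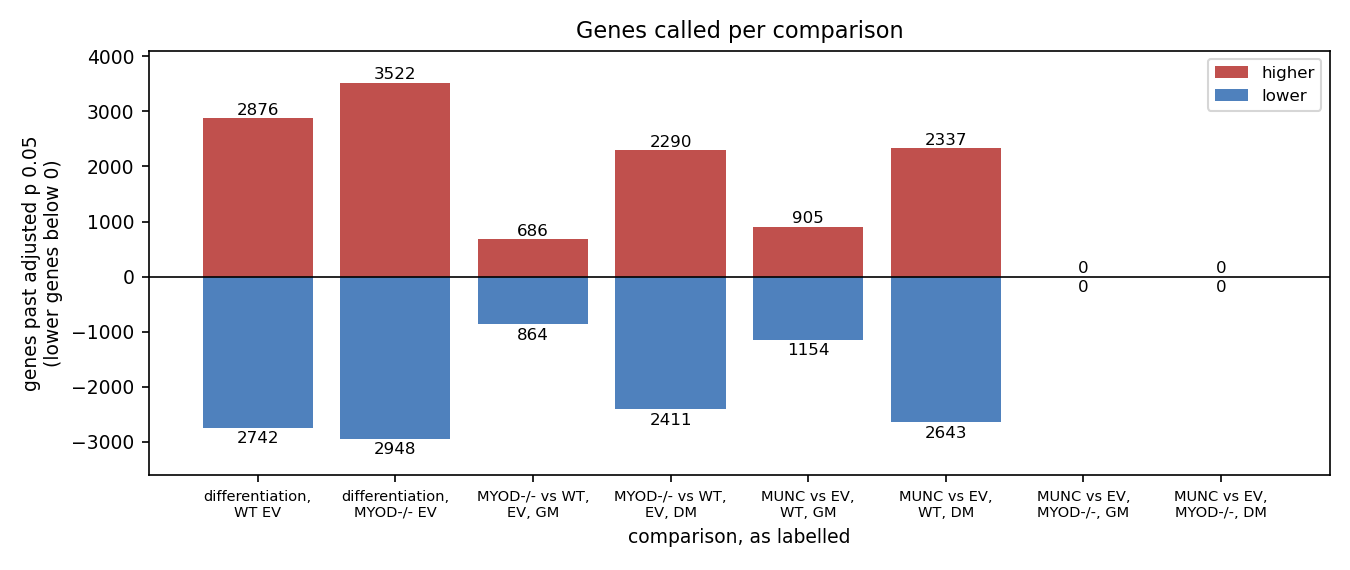
Number of genes called higher and lower (adjusted p under 0.05, edgeR quasi-likelihood test, 14972 genes tested) in each of the 8 comparisons of 2 groups. The MUNC comparison has 2059 (GM) and 4980 (DM) calls in WT-labelled cells and 0 in knockout-labelled cells in both conditions.

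Because the edgeR test called no gene with MUNC in knockout-labelled cells, 0 genes overlapped between the MUNC calls of the 2 genotype labels or between those calls and the genotype calls, and no overlap test was informative. The genes called with MUNC in WT-labelled cells were therefore looked up in the knockout-labelled cells. The 2337 genes higher in DM (median log2 fold change 1.00), such as Myog and Dysf, had a median of -0.02 in knockout-labelled cells, and the 2643 lower ones (-1.09), such as Dhx58 and Isg15, a median of 0.02. In GM the 905 higher genes (1.12), such as Itpkb, had a median of -0.01 and the 1154 lower genes (-1.16), such as Peg10, a median of 0.02. Differentiation calls and MUNC calls in WT-labelled cells share the EV libraries, so their overlap holds chance values in common. In DM 958 genes rose with differentiation and fell with MUNC, such as Irf9 and Usp18, 497 did the reverse, such as Id3 and Acta2, and 356 rose and 478 fell in both. Independent lists would give 507.7, 428.0, 448.9 and 484.0. The 20 simulations of unchanged groups gave 0 calls, so they do not measure how many shared calls the EV libraries add. The covariance of the fold changes was -0.868 against -0.0933 in the simulations, and the correlation across genes -0.390 against -0.490. In GM, 242 genes rose and 265 fell in both, 279 rose with differentiation and fell with MUNC, and 92 did the reverse, against 173.8, 211.3, 221.7 and 165.7 for independent lists. The covariance was 0.0482 against 0.0998 simulated, and the correlation 0.0289 against 0.512. The controls were not split, since with 2 EV libraries per condition a split leaves no replicated control, so part of any excess may come from the shared controls.

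Of the 24 panel genes fixed beforehand, Mef2c, Pax7 and Cdkn1c were too low to test. Myf5, Myf6, Cdh15, Id1, H19 and Col1a1 passed in none of the 13 tests. Their smallest adjusted p values were 0.101 for Myf5, 0.136 for Myf6, 0.532 for Cdh15 and 0.0874 for Id1 (each in knockout-labelled differentiation), 0.376 for H19 (MUNC, WT-labelled DM) and 0.0919 for Col1a1 (MUNC, WT-labelled GM). Myod1 did not pass on differentiation in either EV line (-0.95 ± 0.96, adjusted p = 0.468 in WT-labelled, and 1.16 ± 0.54, adjusted p = 0.108 in knockout-labelled cells).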

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

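All tests of explanations in this part were chosen after the results were seen, except the test of carry-over of reads, whose prediction was written before. The interaction tests at the end of this part were planned before the data were examined. The first pattern was Myod1, which was lower in WT-labelled than in MYOD-/- labelled EV libraries. Genotype labels exchanged between the libraries stayed open: sarcomere genes rose more on differentiation in the knockout-labelled EV cells (median interaction 3.08), but the WT-labelled MUNC libraries, which an exchange would make knockouts, held 162 to 235 Myod1 counts. Loss of Myod1 expression in the WT-labelled EV line itself stayed open, since the lowest WT-labelled MUNC library held Myod1 at 5.85 times the highest WT-labelled EV library, a difference confounded with MUNC. Labels as given, with normal Myod1 in WT cells and a mutant transcript still made in knockout cells, predicted more Myod1 in the WT-labelled EV libraries. The difference between the labels went against this prediction, by 4.80 on the log2 scale after subtracting 2 SE in the smaller case. It is the contrast that defined the pattern, so it is no separate test of this explanation. A mutant transcript stayed open for the reads in the knockout-labelled EV libraries (11.9 CPM or more), where gene counts do not show a deletion.

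The second pattern was the many MUNC calls in WT-labelled cells beside none in knockout-labelled cells, a biological reading of which would be that MUNC acts differently with and without MYOD. Too little precision in the knockout-labelled comparison was excluded only for the genes called higher in differentiating WT-labelled cells, taken as a set. It was excluded there only for a change near the size seen in the WT-labelled cells, and these genes are not independent replicates. Their median log2 fold change was -0.0201 there, against 1.00 in the WT-labelled cells. For other genes and smaller changes it stayed open. Even Gm45923, with a large difference in the knockout-labelled cells, was not called there. A lower MUNC level in the knockout-labelled lines stayed open, because the mean MUNC level was 26.4 times higher in the WT-labelled MUNC libraries and no line had a matched level. A difference between the WT-labelled EV and MUNC lines that is unrelated to MUNC stayed open. In both conditions 7 genes, Perp and Bckdhb among them, were on in one line and off in the other. On meant 5 CPM or more and off under 0.1 CPM, in both libraries of a group. With off set at under 0.3 CPM, 4 genes were on in the EV line only and 12 in the MUNC line only. Perp and Bckdhb were also off in the knockout-labelled EV line, so their low level there did not come from the MUNC vector. The explanations left open could not be told apart from an effect of genotype, since each combination of genotype and vector has its own stably transfected cells.

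The third pattern was MUNC (Gm45923) in the EV libraries, higher in every replicate 1 library. Carry-over of reads between the libraries of replicate 1 stayed open. The number of genes too low for such carry-over (under 0.25 of the MUNC gene's share) was 17, 5, 25 and 0 in the 4 libraries. At least 5 in each would have argued against it, which the libraries with 17, 5 and 25 reached. In the library with 0, knockout-labelled EV DM, Gm45923 was itself the lowest of the genes compared. It stood at 2.15% of its mean in the other groups' replicate 1 libraries, so that library could not decide the question. No biological explanation was tested.

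The remaining values stand out as differences between groups in how they responded. The MUNC comparison differed between genotype labels for 737 genes in GM and 2708 in DM. In GM this included Myod1, at -5.63. In DM it included Myod1 (-5.72), Myog (-2.68), Mymk (-4.22), Myh3 (-4.41), Ckm (-3.76), Id3 (-5.12) and Acta2 (-2.29). Differentiation differed between genotype labels in EV cells for 387 genes, among them Myh3 (8.94), Acta1 (7.30) and Acta2 (3.75). The MUNC comparison differed between culture conditions in WT-labelled cells for 499 genes, including Myh3 (5.87).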

How the results depend on the processing

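The replicate block in a fit on the compared groups only, leaving out Zrsr1 and Rn28s1, and the alternatives for named genes outside the panel were chosen after seeing the data, and the other alternatives before. Groups of 2 libraries limit every result, since leaving out 1 library leaves a group without replicates. The labels do not say whether replicate numbers pair libraries. Deviations from the group means correlated between groups at -0.0126 to 0.712 (median 0.255), and in 23 of 28 pairs of groups above 0.1. This did not hold for all pairs, so the fit without the block was kept. Every pair at or under 0.1 included the knockout-labelled MUNC DM group (-0.0126 to 0.192). Without that group the lowest correlation was 0.149. The replicates of the other groups thus differed in part alike, which the fit without the block counts in its spread. Across the alternatives for 63 panel results, 452 kept their side of the threshold, 51 lost the call, 1 gained it (Myod1 on differentiation of knockout-labelled EV cells with the replicate block, 1.20, adjusted p = 0.0383) and 0 reversed. Of 3624 for 436 other named results, 3317 kept it, 307 lost the call and 0 reversed. Low counts limit genes such as Myod1 in the WT-labelled EV libraries. Where fewer libraries or a stricter threshold lowered a count, the alternative itself shows why, and elsewhere the cause was not tested.

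Counts of called genes follow, against the main counts of 5618 (differentiation, WT-labelled), 6470 (differentiation, knockout-labelled), 1550 (genotype, GM), 4701 (genotype, DM), 2059 (MUNC, WT-labelled GM) and 4980 (MUNC, WT-labelled DM). With a 2-fold threshold they were 2787, 3332, 928, 2383, 1119 and 2586. With adjusted p under 0.01 they were 3525, 4254, 659, 2493, 921 and 2960. The interactions (main 737 and 2708 for MUNC by genotype in GM and DM, 387 for differentiation by genotype and 499 for MUNC by condition, WT-labelled) then had 288, 1262, 56 and 176. With the replicate block the counts, in the order of the main counts, were 6895, 7672, 2405, 6014, 2987 and 6321. The interactions had 1168 and 3852 (MUNC by genotype, GM and DM), 898 (differentiation by genotype) and 1033 (MUNC by condition). For the alternatives that follow, except leaving out libraries, counts are listed only where they moved from the main count by more than a fixed factor. With the replicate block, groups compared only, they were 2733 (genotype, GM), 6589 (MUNC, WT-labelled GM), 106 (MUNC, knockout-labelled DM, 53 higher and 53 lower), 2427 and 4215 (MUNC by genotype, GM and DM) and 1351 (MUNC by condition). The 106 included Gm45923 (3.03), while the replicate block in the fit on all libraries called 0 for the same comparison. In a fit on only the groups compared, without the block, they were 323 (genotype, GM, 201 higher and 122 lower), 818 (MUNC, WT-labelled GM), 1 (MUNC, knockout-labelled DM), 225 (MUNC by genotype, GM) and 160 (differentiation by genotype).

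With transcripts in place of genes the counts were 1012 (genotype, GM), 2 (MUNC, knockout-labelled GM), 431 (MUNC by genotype, GM), 229 (differentiation by genotype) and 2 (MUNC by condition, knockout-labelled). DESeq2 called 4 (MUNC, knockout-labelled DM), 1263 (MUNC by genotype, GM), 992 (differentiation by genotype) and 1155 (MUNC by condition). With limma on log2(TPM + 1) there were 4 (MUNC, knockout-labelled GM), 3 (MUNC, knockout-labelled DM) and 821 (differentiation by genotype). With no filter on low counts there were 2 (MUNC, knockout-labelled DM).

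Leaving out 1 library at a time gave 3835 to 4675 (differentiation, WT-labelled), 4292 to 5842 (differentiation, knockout-labelled), 702 to 849 (genotype, GM), 2607 to 3823 (genotype, DM), 970 to 1199 (MUNC, WT-labelled GM) and 3140 to 4117 (MUNC, WT-labelled DM). The interactions had 396 to 739 (MUNC by genotype, GM), 1515 to 2401 (MUNC by genotype, DM), 57 to 333 (differentiation by genotype) and 198 to 496 (MUNC by condition).

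Gene lists past the test numbered 4, 11, 3, 12, 7, 11 and 3 (differentiation WT-labelled and knockout-labelled, genotype GM and DM, MUNC WT-labelled GM and DM, and MUNC knockout-labelled DM). For camera with estimated correlation these became 0, 0, 0, 3, 0, 0 and 0. With fry they were 9 and 20 for differentiation, 17 for MUNC in WT-labelled DM and 0 for MUNC in knockout-labelled DM. DESeq2 gave 1 gene called the same way with MUNC in both genotype labels in DM, and 1 gene called with MUNC in knockout-labelled DM and the opposite way for genotype. For MUNC and differentiation calls in WT-labelled cells, the genes called the same way in GM (main 507) were 163 with 2-fold calls, 881 with the replicate block and 774 with DESeq2, and those called opposite ways (main 371) were 169 with 2-fold calls and 639 with the block. In DM, those called the same way (main 834) were 201 with 2-fold calls and 1312 with the block, and those called opposite ways (main 1455) were 761 with 2-fold calls.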

Other observations

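The overlaps given here were chosen after the results were seen. Most genes called both between genotype labels and with MUNC in WT-labelled cells had the same sign. In DM 1201 genes, such as Myog, Dysf and Myh3, were higher in both and 1523, such as Mx1, Perp and Ddit3, lower in both, while 100 and 33 went opposite ways. Independent lists would give 357.4, 425.6, 404.3 and 376.3. Simulated unchanged groups gave 0, which says nothing of how many calls the shared EV libraries add. The covariance of the fold changes was 1.42 against 0.0936 simulated, and the correlation across genes 0.613 against 0.490. In GM the counts were 313 and 474 with the same sign and 31 and 7 with opposite signs, against 41.5, 66.6, 52.9 and 52.2 for independent lists. The covariance there was 0.799 against 0.0993 simulated, and the correlation 0.558 against 0.485. Between conditions, where no library is shared, genotype calls in DM and MUNC calls in GM had 477 genes higher and 624 lower in both and 85 and 31 opposite, with a correlation of 0.389. Genotype calls in GM and MUNC calls in DM had 341 and 461, and 68 and 72 opposite, with a correlation of 0.361. The controls were not split, since with 2 libraries a split leaves no replicated control, and the pairs without a shared library still share the WT-labelled EV line.

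Perp stood at 21.9 ± 4.11 (GM) and 17.2 ± 0.167 CPM (DM) in the WT-labelled EV libraries and at a mean of at most 0.0196 CPM in every other group. Bckdhb stood at 11.5 ± 1.52 and 8.87 ± 0.414 CPM in the WT-labelled EV libraries. No gene was on (5 CPM or more) in one of the knockout-labelled lines and off (under 0.1 or under 0.3 CPM) in the other in both conditions. The imprinted neighbours Peg10 and Sgce stood at 39.0 and 18.6 CPM in the proliferating WT-labelled EV libraries, 34.1 and 23.9 in the knockout-labelled EV libraries, and 0.0950 and 0.232 in the WT-labelled MUNC libraries.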
